A study of Homo sapiens with 8 samples.

How the data were processed

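The series measured 2 human lung adenocarcinoma lines, PC9 and PC9R. PC9 carries an activating EGFR mutation and is sensitive to the EGFR kinase inhibitor gefitinib. PC9R was selected from PC9 with gefitinib over 1 to 2 weeks, per the labels' protocols, and the cells were used at passages 8 to 12. Of the 8 samples, 4 were RNA-seq libraries (2 per line), and the other 4 were 1 DNase hypersensitive site (DHS) library and 1 H3K4me2 ChIP-seq library per line. Samples were grouped by line and assay as the titles give them. Nothing in the labels says that the 2 RNA libraries of a line came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

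MACS2, TopHat, HTSeq and DESeq and the build hg19 are named in the submitters' processing notes, with no version or role; peak threshold, control library, HTSeq mode and annotation release are not given in the sources used here. The deposited RNA files hold whole-number counts per RefSeq transcript accession. The deposited peak files hold 1 list per library with a score per peak, which is the authors' own and whose scale is not stated, so it was used only to describe, rank or filter peaks within its list. No peak lay past the end of a GRCh37 chromosome.

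Counts of the 42811 accessions were summed per gene, with names from the RefSeq gene table of GRCh38.p14 (41552 accessions matched), which was used for names only. Genes with more than 1 accession (8198 of 23371) held only 6.74% to 7.07% of the counts of a library, so low values of such genes were not read as low expression; how shared reads were assigned is not given in the sources used here. This covers MET, AXL, FGFR1 and BCL2L11 and, of the genes given values, FN1 (6 accessions), EGFR (4) and CD68, ERBB2, ERBB3, FRAS1, HMGA2, RPL14, SPRED2, TPM2 and WNT5A (2 each), whose folds compare only the reads counted. Gene positions, transcription start sites (TSS) and transcript GC content came from GENCODE 44 lifted to GRCh37. Total counts were 32515891 and 16013058 in the first and second library of PC9, and 32502455 and 16715426 in those of PC9R.

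Differential expression was tested two-sided with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05) on 12660 genes, with no block. Log2 fold changes are PC9R minus PC9, and standard errors (SE) are the fold change divided by the root of F. CPM are normalized by TMM. The 33 gene lists were fixed before the data were examined and 32 were tested, by camera in limma 3.58.1 with a preset correlation of 0.01. The list of mitochondrially encoded genes had no member in the count table. Named genes followed a rule fixed at the same time: 10 genes always, up to 12 called genes per direction with the largest fold changes (absolute log2 fold change of at least 1, libraries of the lines not overlapping, at least 10 CPM in the higher line), up to 4 called members per list or else up to 2 with the highest mean CPM, and the 3 highest-scored peaks per assay found in 1 line only. As scores of different lists have no common scale, the text ranks these peaks within each list. XIST and Y-linked genes were left out. Some genes and 1 peak that these rules select are not reported.

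After the counts were seen, the first and second libraries were treated as 2 batches, because they differed in depth and in a gradient over GC content. Fold changes are therefore also given within each batch. An alternative listed before the data were examined, with library number in the model and called the fit with a batch term, is shown beside the main result. With 4 RNA libraries it leaves 1 residual degree of freedom, so its p-values rest largely on spread borrowed across genes. The rules for naming genes were applied to that fit too, a choice made after both counts of calls had been seen. A gene with 0 counts in a line is given as a bound from 3 counts over the group, and 1 with 1 to 3 counts as a ratio with its 95% exact counting interval. Intervals and floors cover counting error only.

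Peaks were compared with bedtools 2.31.1 at an overlap of at least 1 bp, and shares have exact 95% binomial intervals. With 1 library per line, differences between lines in peaks have no replicate check and no test. DHS peaks were set against H3K4me2 peaks of the same line and against 100 circular shifts of the peaks within chromosomes. Genes were classed by peaks within 1 kb of the TSS, and the median fold change of a class was compared with 10000 random lists matched on mean expression. Windows of 5 Mb with at least 5 tested genes and 10 DHS peaks were used for regional values.

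Alternatives were RLE and upper quartile scaling, no filter and a stricter filter, the batch term, leaving out each RNA library, DESeq2 1.42.0, limma-voom, a fold change minimum, an estimated correlation or fry for lists, and other peak subsets and overlaps. The scripts were tested on simulated data. For PC9R against PC9 on 12660 simulated genes, the fit without a batch term recovered 0 of 50 genes changed 2-fold, 3 of 50 changed 4-fold, 41 of 50 changed 16-fold and 50 of 50 changed 64-fold, with 0 false calls. The fit with a batch term recovered 33 of 50 changed 2-fold and 50 of 50 at each larger fold, with 13 false calls. Its counts were simulated separately, with a mean per batch and the dispersions of that fit. Those of the other fit had no batch shift and its own dispersions, so the recoveries are not comparable. In simulated data for each fit both of the lists shifted 2-fold were called with the preset correlation and none of the 30 others was called. With an estimated correlation 0 of the 2 were called.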

Results

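The data comprised 4 RNA-seq libraries, 2 of gefitinib-sensitive PC9 and 2 of gefitinib-selected PC9R, and 1 DHS and 1 H3K4me2 peak list per line. DNase hypersensitive sites mark open chromatin, and H3K4me2 marks promoters and enhancers. Total counts were 32515891 in the first and 16013058 in the second RNA library of PC9, and 32502455 and 16715426 in those of PC9R. The design asks how the gefitinib-selected line differs from the sensitive line in expression and chromatin. Only PC9R libraries have a gefitinib exposure in the labels, so effects of the drug and of the line cannot be told apart.

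PC9R expressed genes that were almost silent in PC9, and lost others that PC9 expressed at moderate levels. Of the called genes at a mean of 10 CPM or more in PC9R, the most raised were MAP9, a microtubule-associated protein gene on chromosome 4, and GUCY1B1, which encodes the beta subunit of soluble guanylate cyclase. MAP9 had 2 counts over both PC9 libraries and 98.6 ± 38.8 CPM in PC9R (SD, n = 2), a count ratio of 2085 (95% interval 577 to 17223). GUCY1B1 had 1 count in PC9 and 33.98 ± 14.7 CPM in PC9R, a ratio of 1421 (255 to 56176). MAP9, GUCY1B1 and CTSO, also called higher, are neighbours on chromosome 4, with TSS at 156298117, 156680173 and 156875018. Their calls may therefore not be independent. The regional window that holds them had 4 DHS peaks in PC9 and 75 in PC9R. Its median log2 fold change was 0.53 over 11 tested genes. In the other direction, the extracellular matrix gene TNC went from 176 ± 55.2 CPM in PC9 to 0.324 ± 0.216 CPM in PC9R (log2 fold change -9.16, SE 0.90, edgeR adjusted p = 0.0359). CYBA, which encodes a subunit of the NADPH oxidase, went from 142 ± 101 to 0.171 ± 0.242 CPM (log2 fold change -9.43, SE 1.29, edgeR adjusted p = 0.0388).

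In all, 32 of 12660 genes passed, 24 higher and 8 lower in PC9R. The glucose transporter gene SLC2A3 rose 119-fold, from 1.96 ± 0.817 to 231 ± 105 CPM, and the amino acid transporter gene SLC6A14 rose 233-fold. IVL and CSTA, which encode the cornified envelope proteins involucrin and cystatin A, rose 122-fold and 49.2-fold. ADAM23 rose 82.2-fold, the cathepsin gene CTSO 128-fold, FRAS1 80.2-fold and UNC13B 55.7-fold. The kinase gene HUNK had 1 count in PC9 and a ratio of 573 (102.5 to 22670), and the zinc finger gene ZNF287 had 3 counts and a ratio of 230 (78.2 to 1116). EdgeR adjusted p-values of these genes lay between 0.0359 and 0.0388. Among the lower genes, the cancer-testis antigen gene MAGEA3 had 2 counts in PC9R against 42.4 ± 0.489 CPM in PC9, a ratio of 1099 (304 to 9078), and reads may be shared within its gene family. The LDL receptor family gene LRP1B fell with a ratio of 196 (66.6 to 952), and the GABA receptor subunit gene GABRA3, at 0 counts in PC9R, was at least 187-fold lower. MAGEA3 and GABRA3 lie near each other on chromosome X (TSS at 151938240 and 151619787), so these calls may not be independent either. The regional window that holds both had a median log2 fold change of -0.124 over 52 tested genes. NR2F1, a nuclear receptor gene, fell 44.3-fold, and the tropomyosin gene TPM2 fell 32.6-fold. FRAS1 and TPM2 have 2 accessions each, so their folds compare only the reads counted.

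**Figure D1:**
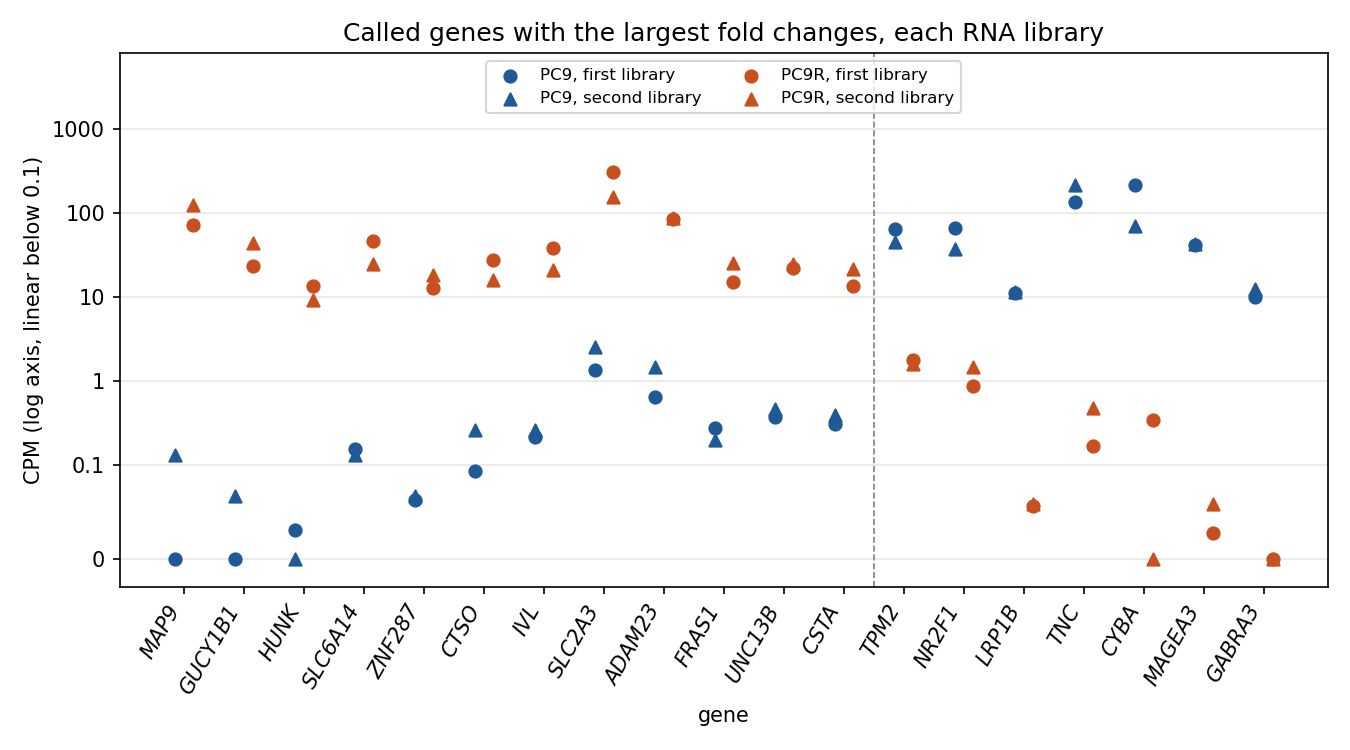
CPM on a log axis (linear below 0.1) of the 19 named genes that passed the test, for each of the 4 RNA libraries. Circles are first and triangles second libraries, blue is PC9 and orange PC9R, and the dashed line parts higher from lower genes. Both PC9R libraries lie on the same side of both PC9 libraries in every gene shown, because the rule that selected the genes required it.

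The first and second libraries differed in depth and along GC content, and they are treated as 2 batches, which the labels do not name. Over the 2952 genes lowest in transcript GC content the second libraries were higher by a median log2 of 0.90, and over the 2950 highest the median was -1.15. Within batches the named calls kept their directions, which the rule for naming them required, so this is no separate support. TNC was at -9.09 in the first and -8.59 in the second libraries, and SLC2A3 at 7.71 and 5.91. With a batch term 2631 genes passed, 1420 higher and 1211 lower, and they included all 32 genes above in the same direction. With so few libraries, p-values of that fit rest largely on spread borrowed across genes. With upper quartile scaling 0 genes passed in edgeR (smallest adjusted p = 0.0536, 919 genes at an unadjusted p under 0.05), against 73 with limma-voom and 381 with DESeq2.

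The EGFR family and its ligands were lower in PC9R as a list (9 members tested, camera adjusted p = 0.00881), although 0 members passed the gene test over all genes and 1, lower, passed adjusted over the list alone. The list was lost with an estimated correlation (adjusted p = 0.861) and, at a median of -1.04, with a batch term and GC correction (camera adjusted p = 0.0505, median -1.01 without the correction). In simulated data the estimated correlation called 0 of 2 lists shifted 2-fold. Failing it, here and for the lists below, thus cannot decide whether a list changed. EGFR, the target of gefitinib, counted here over 4 accessions, was at 1960 ± 130 CPM in PC9 and 776 ± 347 CPM in PC9R (log2 fold change -1.34, SE 0.51, edgeR adjusted p = 0.538). It was lower in both batches, at -1.81 and -1.005, and passed with a batch term (-1.41, SE 0.23, edgeR adjusted p = 0.00448). The 5 Mb window that holds EGFR had a median log2 fold change of -1.27 over 10 tested genes, and the window before it -1.34 over 5. The ligand gene EREG was at 129 ± 84.3 CPM in PC9 and 2.17 ± 1.81 CPM in PC9R (edgeR adjusted p = 0.0606, and 4.01e-05 with a batch term). NRG4 and HBEGF also fell with a batch term (log2 fold changes -2.05 and -1.01), while ERBB2 and ERBB3 were at 0.20 and 0.05 and did not pass.

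Antigen presentation genes were higher in PC9R as a list (10 tested, median log2 fold change 1.21, camera adjusted p = 0.000311), but not with an estimated correlation (adjusted p = 0.861). None passed over all genes, 2 passed adjusted over the list alone, and 8 rose with a batch term. HLA-E, HLA-B, PSMB9 and HLA-DMA are neighbours on chromosome 6, with TSS from 30457286 to 32920874. Members may therefore not be independent, while camera assumed a correlation of 0.01. The regional window that holds these 4 genes had a median log2 fold change of 0.009 over 121 tested genes. HLA-B, a class I heavy chain gene whose reads may be shared with related HLA genes, was at 15.1 ± 9.65 CPM in PC9 and 268 ± 157 CPM in PC9R, and it rose 18.1-fold with a batch term (edgeR adjusted p = 5.48e-05). B2M, the class I light chain gene, rose 2.49-fold with a batch term, and the immunoproteasome gene PSMB9 rose 3.62-fold. HLA-DMA, which acts in class II loading, rose 7.36-fold. Interferon response genes were higher as a list too (22 tested, median 0.81, camera adjusted p = 0.00963), with 0 members passing and, with a batch term, 10 higher and 2 lower. This list was lost with an estimated correlation (adjusted p = 0.861) and, at a median of 0.84, with a batch term and GC correction (camera adjusted p = 0.0505, median 0.83 without the correction). MX2 rose 11.2-fold, IFITM2 8.07-fold and the transcription factor gene IRF1 3.07-fold with a batch term, while BST2 fell 5.26-fold. Without the first PC9R library only antigen presentation of the 3 called lists passed.

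**Figure D2:**
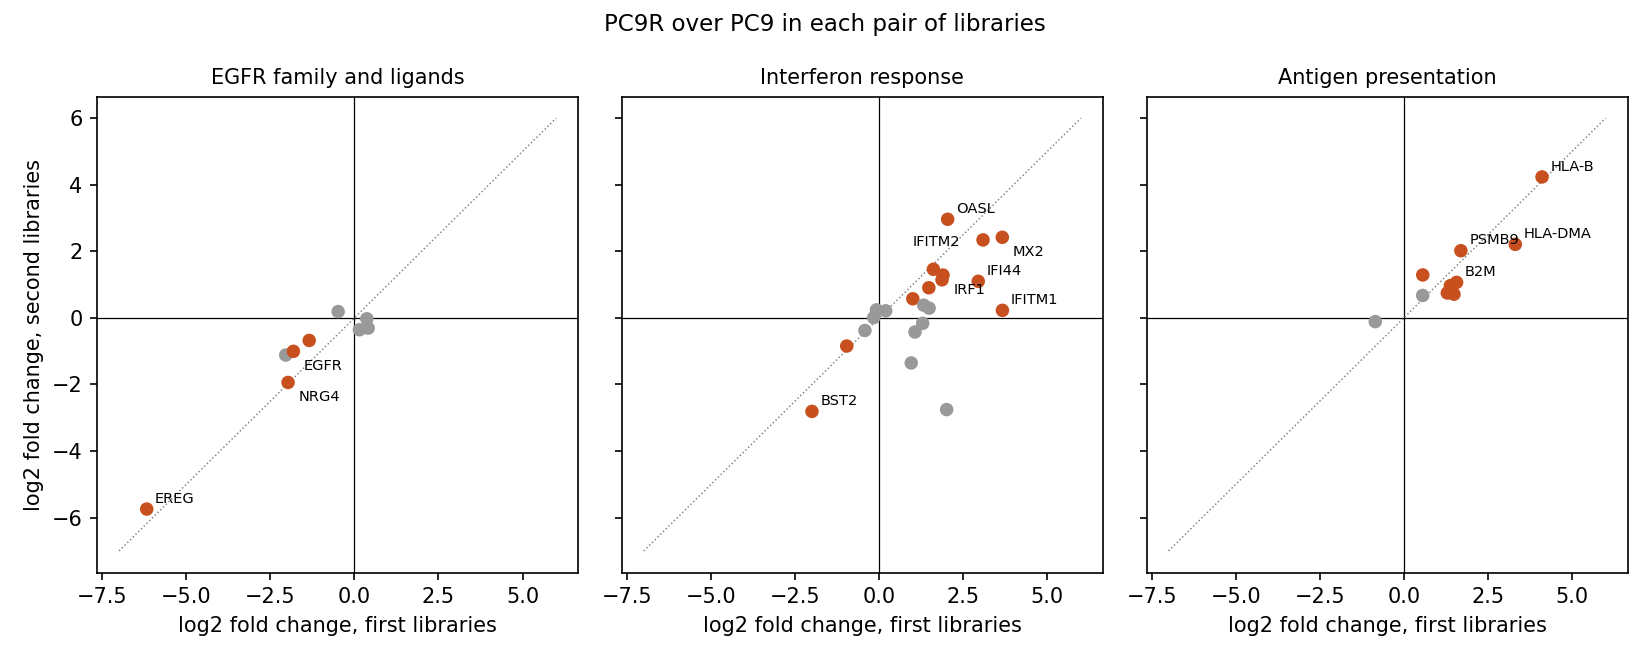
Log2 fold change of PC9R over PC9 between the first libraries (x axis) and between the second libraries (y axis) for members of the 3 called lists. Orange points passed with a batch term and grey points did not; the dotted line marks equal values. EREG lies at -6.18 and -5.74, and HLA-B at 4.11 and 4.23.

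The other lists did not pass in the main test. G2/M cell cycle genes (24 tested, median -0.36, camera adjusted p = 0.054) and ribosomal protein genes (29 tested, median -0.39, camera adjusted p = 0.0503) passed as lower with a batch term, at camera adjusted p = 0.0278 each. With an estimated correlation each had adjusted p = 0.898 in that fit, and with GC correction added G2/M genes did not pass (camera adjusted p = 0.0505, median -0.49 against -0.50). Of these lists, 0 G2/M genes and 4 ribosomal protein genes, among them RPL14 and RPL5, fell as single genes with a batch term. Within both batches 11 of the 24 G2/M genes were lower and 0 higher, and 24 of the 29 ribosomal protein genes were lower and 2 higher. Epithelial markers (23 tested, camera adjusted p = 0.878) and mesenchymal markers (15 tested, camera adjusted p = 0.405) did not pass. CDH1, the epithelial cadherin gene, was at 374 ± 17.4 CPM in PC9 and 592 ± 106 CPM in PC9R (log2 fold change 0.66, SE 0.48, edgeR adjusted p = 0.999). With a batch term CDH1 passed as higher (0.65, SE 0.19, edgeR adjusted p = 0.0474), and in that fit 3 epithelial markers were higher and 1 lower. VIM was near 0 in both lines, with at most 15 counts in a library. Of mesenchymal genes, TNC fell in the main test, and with a batch term FN1 (6 accessions, 20 counts over both PC9 libraries) rose 19.2-fold in the reads counted and TWIST1, at 0 counts in PC9, was at least 19.6-fold higher. IGF1R, a bypass receptor gene, was at -0.27 (SE 0.56, edgeR adjusted p = 0.999). Leukocyte, endothelial and fibroblast marker lists had 2, 4 and 3 tested members, with median log2 fold changes of 0.68, 0.70 and 1.37, and did not pass, at camera adjusted p = 0.451, 0.405 and 0.405. With a batch term 1 member of each list rose (CD68, CDH5 and COL1A1).

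The DHS lists differed more in content than they shared. PC9R had 59600 peaks over 14.9 Mb and PC9 had 19648 over 4.99 Mb, a ratio of 3.03. Of the PC9 peaks 43.2% (95% interval 42.5 to 43.9) overlapped a PC9R peak, and of the PC9R peaks 14.3% (14.0 to 14.5) overlapped a PC9 peak, with a Jaccard index of 0.108. The excess lay outside promoters: PC9R had 1.54 times as many peaks within 1 kb of a coding TSS, but 3.97 times as many elsewhere in gene bodies and 3.54 times as many in intergenic sequence. Shared PC9R peaks lay at promoters in 50.8% of cases, and peaks found in PC9R only in 11.5%. The 3 highest-scored peaks found in PC9 only lay in TRIP13 (chromosome 5, 912369 to 913016, score 55.6), 328 bp from the TSS of PPP6R1 (chromosome 19, 55770432 to 55770995, score 47.0) and at LENG1 and TMC4 (chromosome 19, 54663272 to 54663851, score 44.3). The highest-scored peak found in PC9R only lay within EGFR (chromosome 7, 55160373 to 55160582, score 28.1). That region was dense in DHS peaks in both lines, with 403 in PC9 and 417 in PC9R within 1 Mb of EGFR. With the lists set to equal numbers, 26.1% of PC9 and 25.3% of PC9R peaks overlapped.

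Most H3K4me2 regions of each line overlapped one of the other line. PC9R had 117861 peaks over 60.3 Mb and PC9 had 85246 over 71.4 Mb, so PC9R peaks were more numerous but narrower (median 395 bp against 546 bp). Of the PC9 peaks 70.2% (69.9 to 70.5) overlapped a PC9R peak, and of the PC9R peaks 59.1% (58.8 to 59.4) overlapped a PC9 peak, with a Jaccard index of 0.409. Promoters made up 29.2% of the shared PC9 peaks and 6.72% of those found in PC9 only. The 2 highest-scored peaks found in PC9R only were intergenic, on chromosome 1 (121484127 to 121485536, score 167) and chromosome 7 (61968796 to 61969684, score 127). They lay 647075 and 1489988 bp from the nearest coding TSS. No filter for repeat sequence was applied, so these peaks may not mark regulatory regions. At a reciprocal overlap of 50% the shared parts were 40.3% of PC9 and 29.1% of PC9R peaks.

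**Figure D3:**
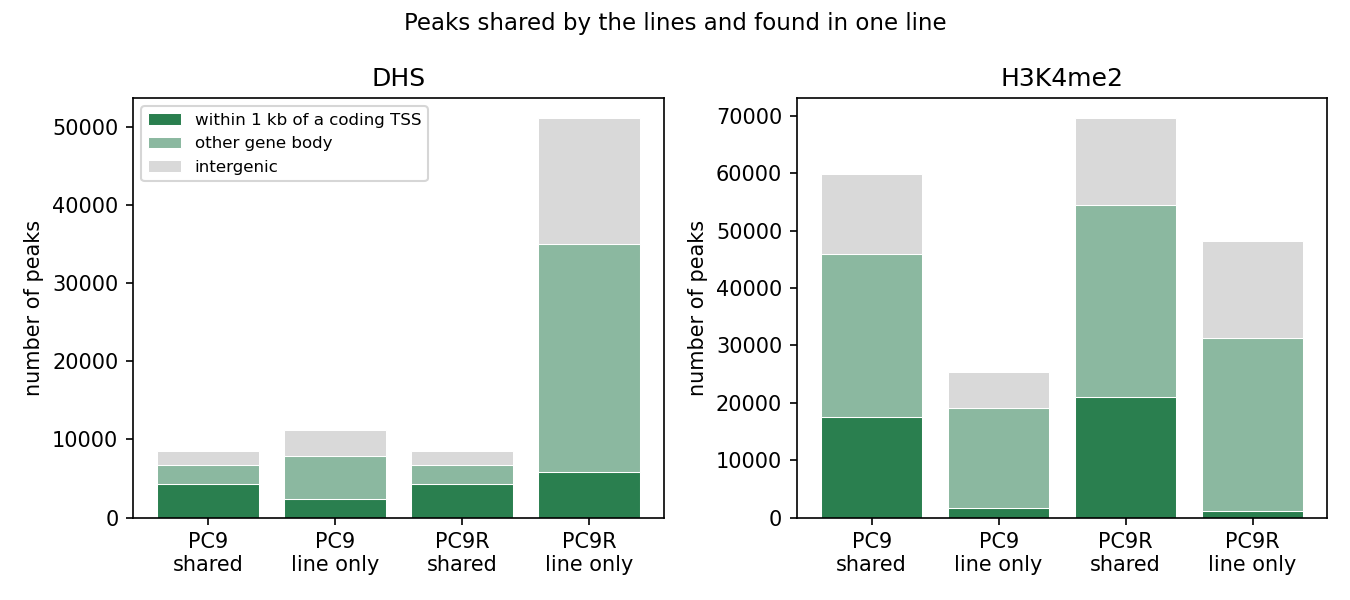
Number of DHS peaks (left) and H3K4me2 peaks (right) shared with the other line or found in one line only, coloured by position. The PC9R-only DHS class, with 51103 peaks, exceeds the other DHS classes and lies mostly outside promoters.

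DHS peaks coincided with H3K4me2 in both lines far above shifted peaks. In PC9 52.2% (51.5 to 52.9) of DHS peaks overlapped H3K4me2, against a mean of 3.34% for shifted peaks. In PC9R the share was 25.8% (25.4 to 26.2), against 3.28%. Shared DHS peaks lay in H3K4me2 at 62.2% in PC9 and 64.8% in PC9R, while DHS peaks found in one line only did so at 44.6% in PC9 and 19.3% in PC9R. PC9-only DHS peaks overlapped the H3K4me2 of PC9R nearly as often (43.6%), and PC9R-only DHS peaks that of PC9 at 16.1%. Of the PC9R-only peaks 2485 lay in H3K4me2 of PC9R alone and 867 in that of PC9 alone, against 632 and 746 of the PC9-only peaks.

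Genes with promoter H3K4me2 in PC9R only had higher expression there. Their median log2 fold change was 0.97 over 157 genes, above all 10000 random lists, and with a batch term 66 of them rose and 4 fell. The 148 genes with promoter H3K4me2 in PC9 only had a median of -0.17, at percentile 0.21, and with a batch term 21 rose and 26 fell. For DHS peaks the medians were smaller, 0.13 over 2142 genes with a promoter peak in PC9R only and -0.20 over 1179 genes with one in PC9 only, both outside the range of the random lists' middle 95%. The 4478 genes with a promoter DHS peak in neither line also lay above that range, at a median of 0.081, and with a batch term 15.7% of them rose against 16.7% of the PC9R-only class. The random lists took no account of position, and no lists matched on region were run. Expression and DHS peaks also moved together by genome region, at a Spearman correlation of 0.634 over windows. For expression and H3K4me2 peaks it was 0.467 over 522 windows, above the 95th percentile of shifted windows (0.132). For the classes of either mark, lying outside the random range thus cannot separate a link with promoter peaks from a regional shift. Of the 24 genes called higher in PC9R, 12 had a promoter DHS peak in PC9R only and 11 in neither line, while 10 had promoter H3K4me2 in PC9R only and 13 in both lines. Of the 8 lower genes, 1 had a promoter DHS peak in PC9 only and 1 in PC9R only, while 2 had promoter H3K4me2 in PC9 only, 4 in both lines and 1, GABRA3, in PC9R only. MAP9, GUCY1B1, ZNF287 and CSTA had both marks at the TSS in PC9R and neither in PC9. NR2F1 had both marks in PC9 and neither in PC9R. TNC had H3K4me2 at its TSS in both lines and a DHS peak there in PC9R only, where it was lower, and EGFR had both marks in both lines.

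**Figure D4:**
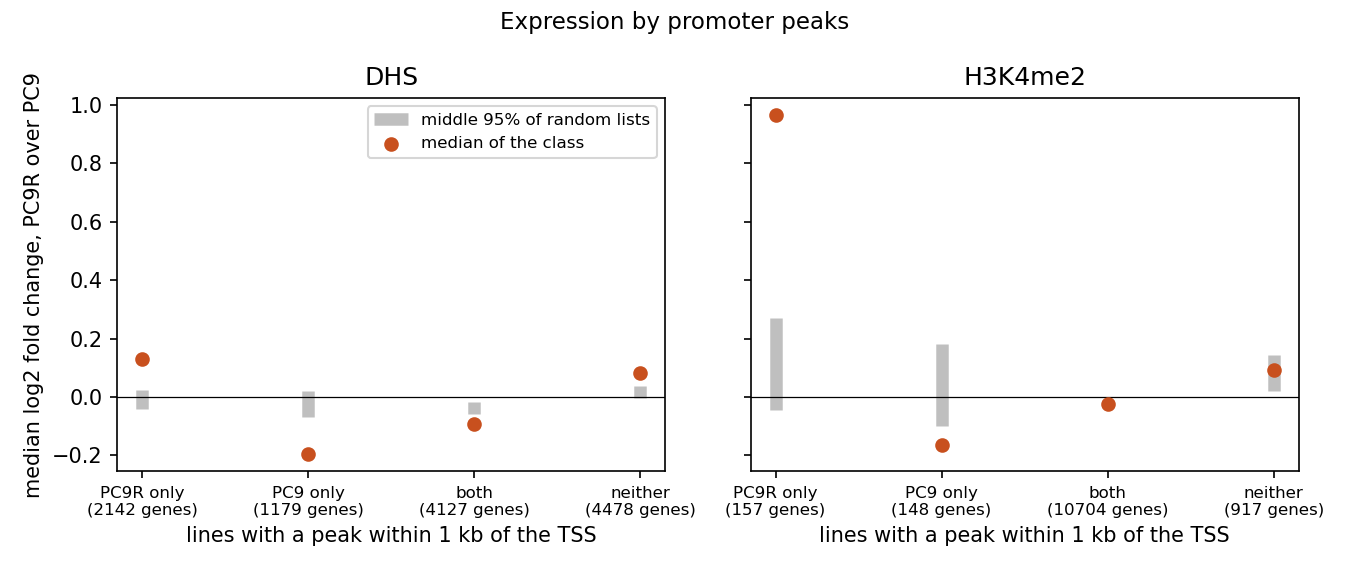
Median log2 fold change of PC9R over PC9 (orange points) for genes classed by which line had a peak within 1 kb of the TSS, for DHS (left) and H3K4me2 (right). Grey bars span the middle 95% of random lists matched on expression but not on position. The PC9R-only H3K4me2 class lies at 0.97, above its bar, which ends at 0.27.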

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

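The fits with GC correction, with a batch term and a fold change minimum, per accession, and without dense windows were chosen after seeing the data. No call of a named gene, list or promoter class changed direction under any alternative run, but values that passed in neither fit changed sign in some, as TOP2A did (0.217, and -1.145 without the second PC9R library). Against 32 genes (24 higher, 8 lower), 0 passed with upper quartile scaling in edgeR (0 higher, 0 lower; 919 at an unadjusted p under 0.05), 440 with no filter (312 and 128), 381 with DESeq2 (261 and 120) and 73 with limma-voom (54 and 19). Leaving out 1 library gave 83 to 254 genes (58 to 216 higher, 25 to 43 lower), and the line left with 1 library is then assumed to vary like the other. The cause was not tested. RLE scaling (41), the stricter filter (31), single accessions (31) and a fold change minimum stayed within 1.5 times. The libraries share only a number, and the second-minus-first differences correlated between lines at 0.788. With the replicate block 2631 genes passed (1420 and 1211), with the replicate block and GC correction 2579 (1383 and 1196, of which 2493 were among the 2631), and with the replicate block and a fold change minimum 1839 (1087 and 752). The block lowered the biological coefficient of variation from 0.498 to 0.18. Of 161 named genes, 103 passed with the block that had not passed without it, and 19 calls were lost with upper quartile scaling.

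Against 3 gene lists, 5 passed with upper quartile scaling, 5 with no filter, 5 with the replicate block, 2 with the replicate block and GC correction (antigen presentation and ribosomal proteins, with the EGFR family, interferon and G2/M lists lost) and 2 to 5 without 1 library. With an estimated correlation 0 lists passed (0 at an unadjusted p under 0.05) and with fry 0 (4), and with the replicate block 0 (0) and 0 (8). The estimated correlation also called 0 of 2 shifted lists in simulated data, so its result cannot decide whether a list changed. Of the 4 RNA libraries, leaving out the first of PC9R lost the EGFR family and interferon lists. Without a block, ribosomal proteins passed with RLE, upper quartile scaling, no filter and without the second PC9 library, and G2/M genes with upper quartile scaling, no filter and without the first PC9 or second PC9R library. Squamous and basal markers passed as higher without the second PC9 library or the first of PC9R.

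For DHS peaks the PC9 share, PC9R share and Jaccard index were 40.9%, 13.6% and 0.109 in the higher-scored part, 26.1%, 25.3% and 0.136 at equal numbers, and 54.5%, 19.9% and 0.132 with peaks widened by 500 bp. At a reciprocal overlap of 50% the shares were 28.8% and 9.49%, and without dense windows the PC9R share was 12.9% and the index 0.098. For H3K4me2 they were 77.1%, 64.4% and 0.408 in the higher-scored part, 62.9%, 70.6% and 0.415 at equal numbers, and 85.8%, 64.8% and 0.491 when widened, with shares of 40.3% and 29.1% at the reciprocal overlap. The share of DHS peaks in H3K4me2 was 43.1% in PC9 and 23.8% in PC9R with the peak covered to 50%, and 29.9% in PC9R at equal numbers. Medians of the promoter classes with a peak in 1 line only kept their direction and side with a window of 5 kb and at equal numbers, and the classes with peaks in both lines or neither were not run there. With 1 library per line, depth sets the number of peaks to an unknown extent.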

Other observations

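Tests of GC content, copy number and descent were chosen after the results they bear on had been seen. With a batch term, further genes changed that the report does not describe. ALDH1A1, an aldehyde dehydrogenase gene used as a stem-like marker, rose 23.7-fold. TGF-beta-responsive TGFBI rose 4.13-fold, while LTBP2 and TGFB1 fell (log2 fold changes -1.82 and -1.22). The glycolytic gene HK2 fell 5.78-fold and the hypoxia marker CA9 fell 5.37-fold, opposite to SLC2A3 of the same list, in which 3 members were higher and 6 lower. The mucin gene MUC5B fell 42.7-fold, and HMGA2, a chromatin architectural gene, fell 24.5-fold. The Wnt antagonist DKK1 fell 5.84-fold and the ligand gene WNT5A rose 11.3-fold. Of MAPK output genes 1 rose, EMP1 by 5.25-fold, and 6 fell, among them SPRED1, SPRED2 and PHLDA1 (-1.52, -1.24 and -0.95), and that list had camera adjusted p = 0.0992 without and 0.103 with a batch term.

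The second RNA libraries of both lines differed from the first in the same genes. Depth as the whole cause is argued against, since after thinning the first libraries the differences still correlated between lines at 0.78 across genes, which are not independent. Transcript GC content is a candidate explanation, with a Spearman correlation of -0.736 across genes, and no biological explanation was tested.

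PC9R had 3.03 times as many DHS peaks as PC9. Caller noise spread evenly along chromosomes is argued against as the whole cause, because peaks found in PC9R only lay in H3K4me2 5.97 times as often as shifted peaks. Only 19.3% of them lay in it, and 11.7% of those outside promoters, for which no shifts were run. Noise that gathers in open chromatin would also exceed shifted peaks, so the shifts cannot exclude it. A deeper or looser call may account for part, as the median score of peaks found in PC9R only was 0.729 of that of shared PC9R peaks. Peaks found in PC9 only also scored below shared PC9 peaks, at medians of 5.98 and 7.32. A lower score is thus not particular to the line with more peaks. A deeper or looser call alone leaves the 11153 PC9 peaks with no PC9R counterpart open. A difference between the lines stays open as well, untested with 1 library each.

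Expression and DHS peaks moved together by genome region. Over 515 windows of 5 Mb the median fold change and the log2 ratio of DHS peaks had a Spearman correlation of 0.634, above the 95th percentile of shifted windows (0.112), which is consistent with copy number differences between the lines. Promoter peaks of the changed genes and the GC gradient between libraries are argued against as causes, since the value was 0.585 without peaks near genes, over the 375 windows that kept enough peaks, and 0.64 with GC-corrected fold changes. Descent of PC9R from another line stays open: the lines shared 5 of their 10 densest DHS windows against 0.161 by chance, but windows rich in repeats may be dense in unrelated lines too, and no such line was analysed here. Copy number itself was not measured.

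By chromosome, the median log2 fold change was -0.66 on chromosome 13 and -0.35 on chromosome 3, where the DHS ratios were 1.14 and 1.68. It was 0.39 on chromosome 20 and 0.25 on chromosome 9, with DHS ratios of 5.44 and 6.99. Chromosome 17, at 0.31, had a DHS ratio of only 3.12, and chromosome 4, with a ratio of 4.78, a median of 0.03. The region within 1 Mb of EGFR held 403 DHS peaks in PC9 and 417 in PC9R, or 2.05% and 0.70% of each list, in 0.071% of the genome. On chromosome 3 the window from 105000001 to 110000000 held 669 DHS peaks in PC9 and 428 in PC9R. The mitochondrial genome held 10 DHS peaks in each line.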
